A study of Mus musculus with 5 samples.

How the data were processed

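Single-cell transcriptomes of mouse mesoderm were measured by Drop-seq, in which each cell is captured in a droplet with a barcoded bead and the 3′ ends of its transcripts are counted by unique molecular identifier (UMI). The series holds 5 libraries of cells sorted for marking by Mesp1-Cre, a driver active in nascent mesoderm. In 2 of them (WT 1 and WT 2) the marked cells carried a tdTomato reporter. In another 2 (Gli3R 1 and Gli3R 2) they carried a Cre-dependent transgene for Gli3R, the repressor form of the transcription factor Gli3, which dominantly represses Hedgehog target genes, joined to a Venus reporter. Cells of both genotypes were pooled during sorting for the fifth library (Mix 1), at about equal numbers at the outset per the labels. Per the labels' protocol, embryos were pooled with their littermates, dissociated with an enzyme and sorted with a dye that excludes dead cells, and the droplets were smaller than in the standard method. The labels disagree on embryo age. The age given is embryonic day 8.25 for WT 1, WT 2 and Gli3R 1, 7.5 for Mix 1 and 7.5 for Gli3R 2, whose source name gives 8.25, while the protocol gives 8.25 for every library. Nothing in the labels says how many litters entered a library, so p-values measure the spread between these libraries, which may be technical in part.

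The deposited tables hold UMI counts per gene and cell barcode, as raw whole numbers with no normalization. The authors made these counts with UMI-tools, cutadapt, STAR and featureCounts on the mouse genome build mm10, per the submitters' processing notes. Versions, the annotation release, strand settings and any filter on genes or cells are not given in the sources used here. The authors also deposited read counts per accepted barcode, from before mapping. The tables list 7494 to 7500 barcodes per library and 33774 gene identifiers in all. Symbols and positions came from GENCODE M21 on mm10, which paired 99.8% of the identifiers with a symbol. Where several identifiers shared a symbol, the one with the most UMIs kept it and the others stayed separate. No transgene, reporter or Cre sequence was analysed here. Processed pseudogenes share sequence with their parent genes, so their counts depend on how the authors' counting assigned shared reads and are uncertain.

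Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were taken as cells. Doublets were called per library with the Scrublet method in scanpy 1.11.5 (expected rate 0.05) and removed. They made up 0.423%, 2.02%, 2.91%, 2.35% and 0.458% of the passing barcodes of WT 1, WT 2, Gli3R 1, Gli3R 2 and Mix 1. Whether the low rates of WT 1 and Mix 1 reflect few doublets or a caller that missed them was not tested, so doublets may remain there. Barcodes that share their first 11 bases with another barcode of the library, which can split one bead into several, made up 1.73% of WT 1, 3.29% of WT 2, 3.45% of Gli3R 1, 7.43% of Gli3R 2 and 12.5% of Mix 1. They were kept, and merged in an alternative.

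Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen across the 4 single-genotype libraries. Sex-linked, mitochondrial, ribosomal protein and cell cycle genes were left out of that choice, as were the lists of Hedgehog, FGF ligand and FGF/ERK response genes, so that class sizes did not rest on them. Cells of these libraries were joined by 15 nearest neighbours on 30 principal components and clustered by the Leiden method at resolution 1 without batch integration, giving 25 clusters. Cells of Mix 1 took the cluster of their nearest neighbours. Clusters were named from 22 marker lists fixed before the data were examined, where at least 3 markers of the list stood among their 50 genes of highest fold over the other classes; that number was set after the clusters were seen. This gave 10 named classes. Clusters 17 and 20 stayed unnamed and were compared by number, and 3 small clusters were left out. Cluster 20 was left unnamed although its 10 leading genes hold 3 of the gut endoderm list (Epcam, Cldn6 and Trh), beside the neural marker Pax6. Class names are these markers' and may differ from the study's own.

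Libraries, not cells, were the replicates, and Gli3R was compared with WT, 2 libraries against 2. The share of cells per class was tested over 12 classes with the quasi-likelihood test of edgeR 4.0.16 on cell counts, with the library's cell total as offset. An exact two-sided permutation test of 2 against 2 libraries was run beside it and cannot give a p below 0.33. UMI counts were summed over all kept cells of a library, and over each class with at least 20 cells in each of the 4 libraries (10 classes). The sums were tested with edgeR's quasi-likelihood test after its filter on low counts and TMM scaling. Every adjusted p is a Benjamini-Hochberg value with a threshold of 0.05, within classes for shares, within one set of cells for genes, and from edgeR unless a list test is named. Log2 fold changes are Gli3R over WT. Standard errors are the log2 fold change divided by the root of the test's F. CPM values are UMIs of the gene per 1000000 UMIs of the cells summed, without TMM factors. The median log2 fold change of all genes in the whole libraries was -0.02 with TMM, -0.05 with DESeq2 size factors and 0.13 with plain totals.

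A total of 28 gene lists (signalling pathways, mesoderm and blood cell types, cell cycle, stress and cells outside the sort gate) were fixed together with the marker lists. They were tested as sets with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM, adjusted over the lists with at least 3 measured members. Their members were also adjusted over the list alone. The text names genes by a rule fixed at the same time. In the whole libraries these are the 10 highest and 10 lowest log2 fold changes past the threshold with a mean of at least 20 CPM and no overlap between genotypes, and within a class the first 5 each way. Where fewer than 5 genes passed, the 5 with the smallest p are given too. Of each list, the 4 members with the smallest p may be named, and every member of the Hedgehog, FGF ligand and FGF/ERK response lists. Sex-linked, ribosomal protein and predicted genes enter only as counts. Other genes are said to have been chosen after their values were seen. Mix 1 is a single library of both genotypes and entered no test. Its shares carry exact binomial and its CPM exact Poisson intervals at 95%, which cover counting error only. A count of 0 was replaced by a floor of 3 counts over the group where a fold is given.

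The main alternatives were UMI minimums of 500 and 2000, doublets kept, resolutions of 0.5 and 2, the pathway lists included in clustering, scaling within libraries, TMM over classes, blood cells left out, DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, all barcodes, class-weighted sums, the replicate number as a block, camera with an estimated correlation, fry, and each library left out in turn. Cells of WT 1 to Gli3R 2 were 4002, 7309, 7161 and 6183, with 5219 in Mix 1, and their median depth was 3232, 3547, 2648, 2529 and 3647 UMIs.

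The tests were checked on simulated data. In a simulation of the whole libraries on 17479 genes, 2.04% of genes changed 2-fold and 49.0% of genes changed 4-fold were called, with 4 of 17285 unchanged genes. In simulated erythroid-like cells on 13081 genes these shares were 8.51% and 60.6%, and in simulated somite-like cells on 7059 genes 4.65% and 71.9%. In 200 simulated sets of the 12 classes for each size, the somite-like class was called in 37.5% when 4-fold larger and in 71.5% when 8-fold larger. No other class was enlarged, and all were drawn with a common dispersion, so power for classes of other size or spread was not simulated. A list raised 2-fold was found by camera at the preset correlation in each of the 3 simulations. Fry found it in the simulation of the whole libraries alone. Camera with an estimated correlation found it in none of the 3, so that test had little power in these simulations. Genes were drawn independently of each other there. The simulations therefore do not show how often the preset correlation calls lists falsely where genes vary together. The work used Python 3.11.15, R 4.3.3, numpy 2.4.6 and scipy 1.17.1.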

Results

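Single mouse mesoderm cells marked by Mesp1-Cre were profiled by Drop-seq to compare the cell composition and gene expression of mesoderm in which Hedgehog targets are repressed by Gli3R with those of control mesoderm. There were 2 WT libraries, 2 Gli3R libraries and 1 library pooled from both genotypes (Mix 1). They held 17323792 and 31545501 UMIs (WT 1 and WT 2), 25459617 and 21211237 (Gli3R 1 and Gli3R 2) and 31481422 (Mix 1), sequenced to 4.21, 1.83, 2.23, 2.97 and 1.87 reads per UMI. After filtering they held 4002, 7309, 7161, 6183 and 5219 cells. Native Gli3 (ENSMUSG00000021318, chromosome 13, 15463235 to 15730026, plus strand) stood at 4.15 and 19.2 CPM (UMIs of the gene per 1000000) in WT, 28.1 and 29.0 in Gli3R and 9.75 in Mix 1 (log2 fold change 1.20, SE 0.55, adjusted p = 0.38). A 3′ count of the native gene need not read the truncated transgene, so this level does not check the genotype. Libraries were counted as the samples. Set against counting noise alone, the chi-square per degree of freedom over genes was 185 between the WT libraries and 69.8 between the Gli3R libraries, which does not tell biological from technical spread.

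The first question was how the cell classes of the sorted mesoderm differed between the genotypes. The reporter differed with the genotype, tdTomato in WT and Venus in Gli3R. Differences in shares or genes due to the reporter or its sorting therefore could not be told apart from those due to Gli3R. Blood progenitor and megakaryocyte-like cells were more frequent in Gli3R, at 10.2% ± 2.21 (SD, n = 2) of cells against 0.875% ± 0.212 (SD, n = 2) in WT (log2 ratio 3.55, SE 0.78, adjusted p = 0.0016). Caudal mesoderm-like cells, which express the tail bud genes T and Cdx1, were less frequent, at 0.624% ± 0.402 against 4.30% ± 3.11 (log2 ratio -2.78, SE 0.76, adjusted p = 0.0072, n = 2 each). Visceral endoderm-like cells, marked by Ttr and Afp and foreign to a mesoderm gate, made up 1.94% ± 1.63 of Gli3R and 0.390% ± 0.261 of WT cells (log2 ratio 2.34, SE 0.77, adjusted p = 0.022). Most of them came from Gli3R 2, where they were 3.09% of cells against 0.782% in Gli3R 1. The exact permutation test gave its smallest possible p, 0.33, for each of these 3 classes. None of the 3 passed with the replicate number as a block, though that number gives no known pairing of libraries. The labels disagree on embryo age, and whether a difference in the actual stage of the embryos gave these shares was not tested.

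The other 9 classes did not pass the test. Erythroid-like cells were the largest class in every library except Gli3R 1, with 70.5% of cells in WT 1, 42.3% in WT 2, 19.2% in Gli3R 1 and 34.0% in Gli3R 2 (log2 ratio -1.08, SE 0.70, adjusted p = 0.21). Endothelium-like cells made up 18.1% and 11.9% of Gli3R 1 and Gli3R 2 and 3.12% and 7.11% of WT 1 and WT 2 (log2 ratio 1.55, SE 0.71, adjusted p = 0.12). Log2 ratios were 1.09 for anterior cardiopharyngeal-like cells, 1.01 for posterior heart field and lateral plate-like cells, 0.60 for cardiomyocyte-like cells, 0.51 for extraembryonic mesenchyme and allantois-like cells, 1.31 for unnamed cluster 17, -0.89 for somite-like cells and -1.11 for unnamed cluster 20 (adjusted p 0.20 to 0.47). In the extraembryonic class the genotypes overlapped (exact p = 0.67). Of cluster 20 the leading genes were Epcam, Crabp2 and Otx2, and of cluster 17 Alox5ap and Cd34.

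The blood classes took 71.6% and 43.0% of the WT cells and 27.9% and 45.8% of the Gli3R cells, so a share of all cells moves with them. Among the cells outside the erythroid-like and blood progenitor classes, caudal mesoderm-like cells were at 9.39% ± 2.84 in WT and 0.942% ± 0.447 in Gli3R (log2 ratio -3.30, SE 0.52, adjusted p = 0.012). Cluster 17, whose leading genes include the blood cell genes Cd34 and Laptm5, is counted among these cells. There the visceral endoderm-like share no longer passed (1.64, adjusted p = 0.28), and somite-like (-1.61) and cluster 20 (-1.83) cells both reached an adjusted p of 0.059. Leaving out WT 2 ended the calls of the blood progenitor (3.31, adjusted p = 0.063), caudal (-1.74, 0.12) and visceral endoderm-like class (1.75, 0.16), and leaving out Gli3R 2 those of the caudal (-2.25, 0.23) and visceral endoderm-like class (1.04, 0.43).

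**Figure D1:**
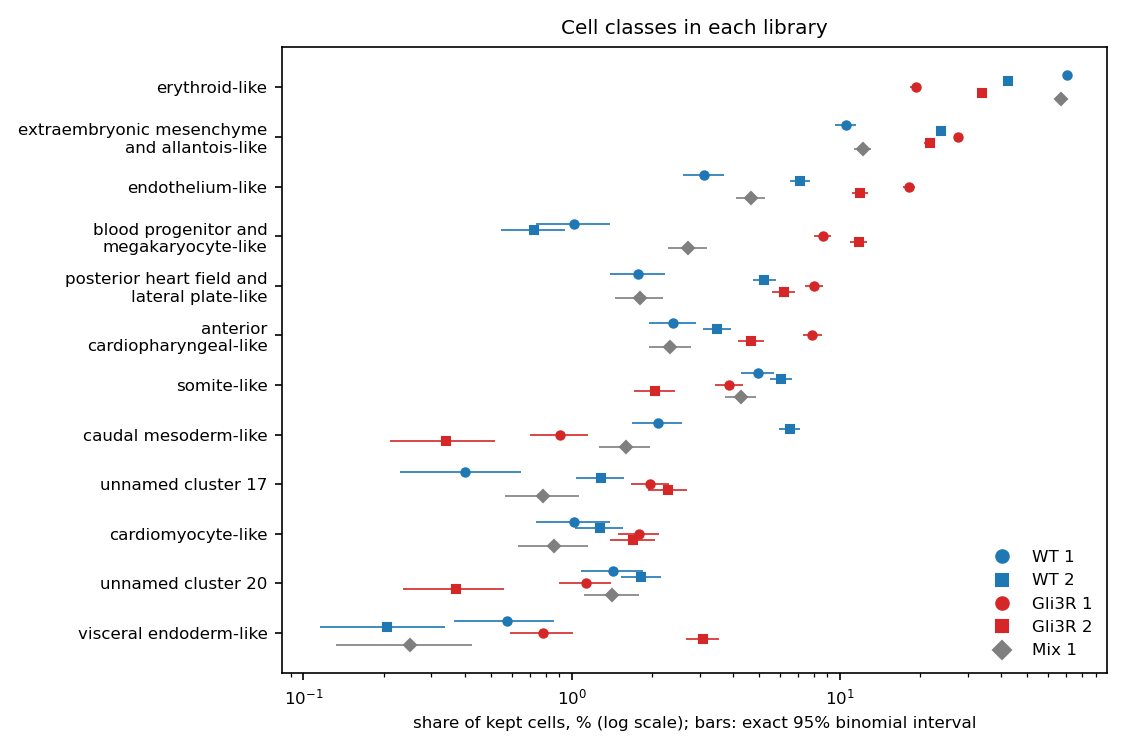
Share of kept cells per class in percent on a log axis, for 2 WT (blue), 2 Gli3R (red) and the Mix library (grey), with exact 95% binomial intervals that cover counting error only. The Gli3R points of the blood progenitor and megakaryocyte-like class lie at 8.63% and 11.8% against 1.02% and 0.725% in WT, and those of the caudal class at 0.908% and 0.340% against 2.10% and 6.50%.

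Over whole libraries, 51 genes were higher and 12 lower in Gli3R. The highest fold change among the named genes was that of Emx2, a homeobox gene of forebrain and urogenital development (ENSMUSG00000043969, chromosome 19, 59458372 to 59465357, plus strand), at 0.252 and 0.391 CPM in WT and 36.0 and 58.1 in Gli3R (log2 6.98, SE 0.49, adjusted p = 0.0062). Pf4, platelet factor 4, rose too (6.60 ± 2.33 against 310 ± 118 CPM, log2 5.34, SE 0.51, adjusted p = 0.019), as did the platelet receptor gene Clec1b (4.24), pleckstrin (Plek, 3.63), serglycin (Srgn, 6.33), the Fc receptor chain gene Fcer1g (4.38) and galectin-9 (Lgals9, 4.46). These are among the leading genes of the clusters that form the more frequent blood progenitor class, and Fcer1g also of cluster 17. Tmem40 (5.90), the kinase gene Nrk (3.36) and Myzap (3.19), which encodes a protein of cardiac cell junctions, completed the 10 highest.

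Among the genes that fell, 4 met the rule for naming. Hspa8, a constitutive heat shock protein (chromosome 9, 40800984 to 40810087, plus strand), went from 673 ± 244 to 58.3 ± 17.6 CPM (log2 -3.77, SE 0.47, adjusted p = 0.034). Alad, an enzyme of haem synthesis, fell by 3.28 on the log2 scale (adjusted p = 0.035) and the planar polarity gene Vangl1 by 2.22 (adjusted p = 0.037). Ptch1, the Hedgehog receptor and a direct target of the pathway (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598, minus strand), fell from 21.96 and 57.3 CPM in WT to 5.16 and 5.49 in Gli3R (log2 -3.01, SE 0.43, adjusted p = 0.045).

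In all, 63 of 18047 genes passed and 2541 had an unadjusted p under 0.05. Of the 63, 24 had a mean of at least 20 CPM and no overlap between genotypes, and 3 of these were sex-linked, ribosomal protein or predicted genes. The count depended on the libraries and on the blood cells. It was 98 without WT 1 (71 higher), 1476 without WT 2 (742 higher and 734 lower), 295 without Gli3R 1 (251 higher) and 203 without Gli3R 2 (161 higher), and 2 with the erythroid and blood progenitor cells left out, where Ptch1 kept its fold change (-3.10, adjusted p = 0.089). With each class set in every library to its mean share over the 4 libraries it was 29. DESeq2 called 702 genes, and 1134 were called with no filter on low counts. Of the 14 named genes 13 kept their call without each library. Vangl1 lost it without Gli3R 1 (adjusted p = 0.056) and without Gli3R 2 (0.053).

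Hedgehog pathway genes stood lower in Gli3R as a list (camera, adjusted p = 0.0070), a call lost with an estimated correlation (adjusted p = 0.87), with fry (0.55) and without WT 2 (0.40). Of 17 measured members, 11 had negative and 6 positive fold changes, and Ptch1 alone passed among all genes. Adjusted over the list alone, 6 fell and 1 rose. Hhip, a feedback inhibitor induced by the pathway, stood at 3.65 and 9.87 CPM in WT and 0.819 and 0.610 in Gli3R (log2 -3.34, SE 0.60, adjusted p = 0.071). The other members past the list threshold were the forkhead genes Foxl1 (-3.10) and Foxf2 (-1.81), Osr1 (-2.19) and the activator gene Gli1 (-1.48). Gas1 was the member that rose (2.15, SE 0.37). It encodes a co-receptor that Hedgehog signalling itself represses. Foxc2 (-1.24), Foxf1 (-1.24), Nkx2-5 (-0.58), Sufu (-0.10), Gli2 (0.35), Cdon (1.08), Smo (0.02) and Boc (0.02) did not pass.

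FGF ligand genes were also lower as a list (adjusted p = 0.0070), with negative values in 7 of 7 measured members, and 2 lower adjusted over the list alone. The list had an adjusted p of 0.87 with an estimated correlation, 0.68 with fry and 0.35 without WT 2. The 2 members were the neighbours Fgf3 (chromosome 7, 144838083 to 144844436; 8.37 and 24.4 CPM in WT, 1.39 and 0.712 in Gli3R, log2 -4.05, SE 0.60, adjusted p over all genes 0.051) and Fgf15 (-3.40, SE 0.89, 0.16). Fgf17 (-1.34), Fgf5 (-1.26), Fgf8 (-0.60), Fgf10 (-0.21) and Fgf18 (-0.05) did not pass. Genes that respond to FGF and ERK signalling did not pass as a list (adjusted p = 0.36), except without Gli3R 2 (0.020). Adjusted over the list alone 1 rose, the immediate early gene Egr1 (1.92, SE 0.31, 0.061 over all genes), and 2 fell, the mesoderm genes T (-2.91) and Tbx6 (-2.67). The rest lay between -0.56 for Spry1 and 1.66 for Ier3, with Spry2 at 1.27, Dusp6 at 0.96 and Spry4 at -0.27. The values of Etv5, Etv1, Etv4, Fgfr1, Fgfr2, Spred1, Spred2, Il17rd and Dusp4 were 0.46, 0.46, 0.09, 0.38, 0.33, 0.33, 0.28, -0.22 and -0.15.

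Among the other lists, the endothelium list rose most clearly (adjusted p = 2.1e-07, 5 of 14 adjusted over the list alone), with Emcn (2.57), Erg (2.86), Esam (2.31) and Tek (1.56), beside an endothelium-like share of 18.1% and 11.9% in Gli3R and 3.12% and 7.11% in WT. With an estimated correlation its adjusted p, and the smallest of any list, was 0.87. Extracellular matrix genes (1.6e-05, 5 of 15) such as Postn (1.65) and Col1a2 (1.79), cardiac contractile genes (0.00032, 1 of 14, Tnni1 at 1.19), cardiac transcription factors (0.010, 1 of 12, Mef2c at 1.95), EMT regulators (0.010, 0 of 8) and BMP response genes (0.015, 0 of 12) were also higher as lists. So was the list of neural and endoderm genes from outside the gate (0.014, 5 of 11), led by the visceral endoderm genes Afp (4.52) and Ttr (3.13), alongside the larger visceral endoderm-like share of Gli3R 2. S phase genes (0.00032, 0 of 20 adjusted over the list alone, Mcm5 at -0.82) stood lower. Somite and presomitic genes (0.010, 2 of 13, Ripply2 at -4.61), early mesoderm genes (0.014, 2 of 9, Cer1 at -3.95) and WNT response genes (0.026, 0 of 14, Cdx1 at -2.45) did so too, alongside the smaller caudal class.

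No other list passed. The adjusted p was 0.10 for dissociation and heat stress, 0.11 for retinoic acid response, 0.26 for allantois, 0.29 for pharyngeal and head mesoderm and for G2/M phase, 0.48 for anterior Hox, 0.86 for Notch response and for haemoglobin and erythroid genes, 0.87 for mitochondrially encoded genes, 0.91 for p53 and apoptosis, and 0.95 for posterior Hox, glycolysis and hypoxia, left-right and sex-linked genes. Median and mean differed in sign for Notch response (0.20 and -0.04), posterior Hox (0.08 and -0.03), mitochondrially encoded (0.22 and -1.04) and sex-linked genes (0.13 and -0.10). Of the 28 lists 13 passed, and 0 did with camera at an estimated correlation (smallest adjusted p 0.87) or with fry (0.55). Without WT 2 the lists of early mesoderm (0.50), somite (0.41) and WNT genes (0.73) lost their call as well, and without Gli3R 2 WNT (0.32) and somite genes (0.095). Without WT 1 BMP (0.19), EMT (0.18) and cardiac factor genes (0.42), and without Gli3R 1 BMP (0.76) and cardiac factor genes (0.21), lost theirs.

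**Figure D2:**
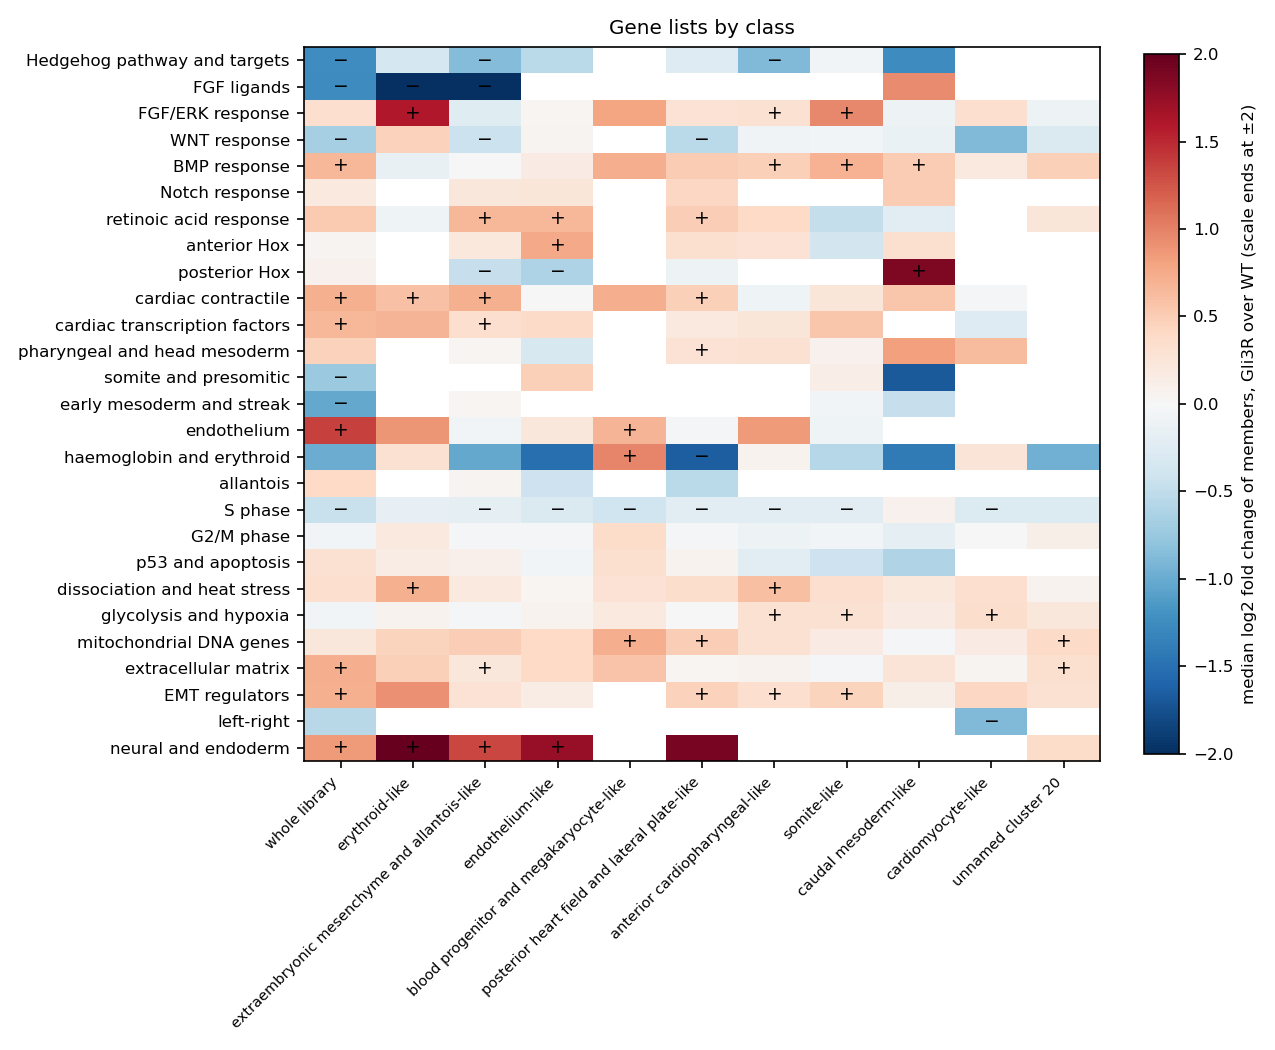
Median log2 fold change of each gene list's members, Gli3R over WT (colour, ends at ±2), in whole libraries and in each class, with + or − where camera at a preset correlation passed an adjusted p of 0.05 and blank cells where fewer than 3 members were measured. The Hedgehog list carries a minus sign over whole libraries and in 2 classes, and the S phase list over whole libraries and in 7 classes.

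The next question was which genes differed within a class, apart from class sizes. Ptch1 could be tested in 7 classes and was lower in both Gli3R libraries than in both WT libraries in 7 of 7, with log2 fold changes of -4.29 to -1.26. It passed in erythroid-like cells (8.80 and 15.4 CPM in WT, 0.527 and 0.607 in Gli3R, log2 -4.29, SE 0.52, adjusted p = 0.011) and in extraembryonic mesenchyme and allantois-like cells (-3.46, SE 0.30, adjusted p = 0.0058). The values that did not pass were -2.93 in somite-like (adjusted p = 0.071), -2.89 in anterior cardiopharyngeal-like (0.088), -2.89 in endothelium-like (0.17), -2.38 in lateral plate-like (0.17) and -1.26 in caudal cells (1.0). Whether these effects differed between classes was not tested. Some Gli3R values rest on few UMIs, such as 6 and 4 in the somite-like cells of Gli3R 1 and Gli3R 2. In erythroid-like cells the genotypes lay largely in separate clusters, as given below. Hhip was lower in both Gli3R libraries than in both WT libraries in 2 of 2 classes. It passed in extraembryonic mesenchyme and allantois-like cells (-4.97, SE 0.42, adjusted p = 0.0058) but not in anterior cardiopharyngeal-like cells (-1.73, SE 0.71, adjusted p = 0.88).

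**Figure D3:**
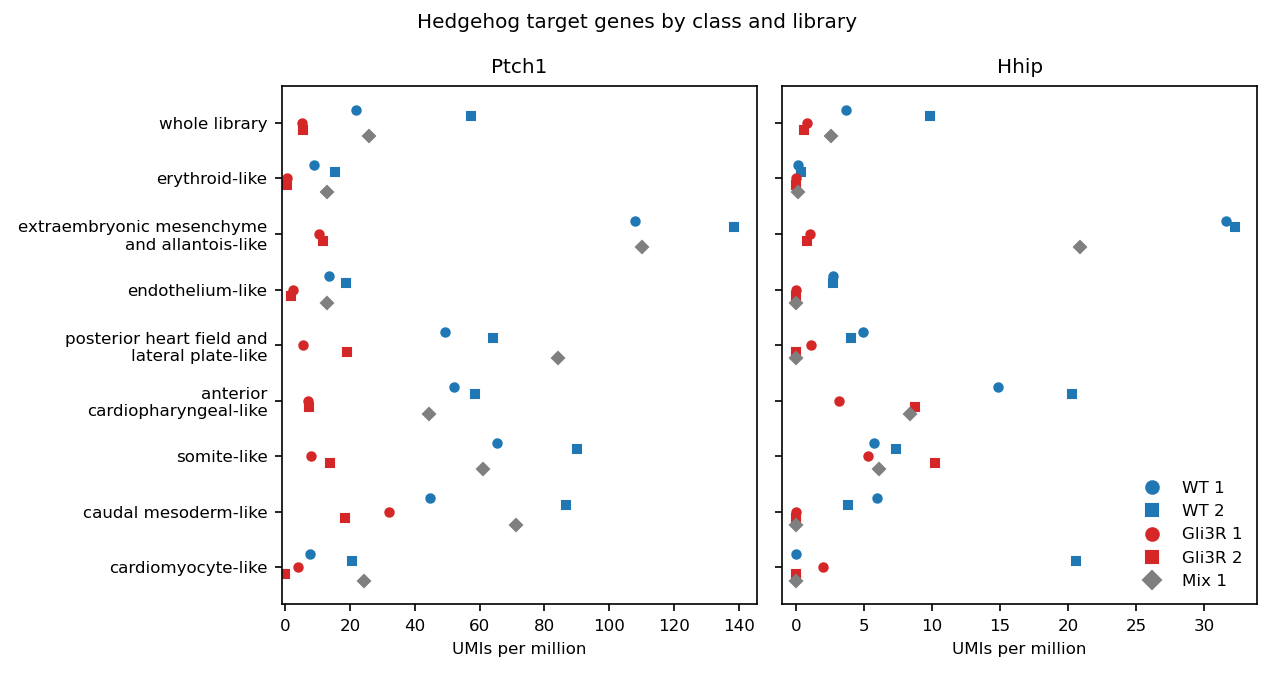
CPM of the Hedgehog targets Ptch1 and Hhip per library, over whole libraries and by class (blue, WT; red, Gli3R; grey, Mix). In extraembryonic mesenchyme and allantois-like cells Ptch1 stands at 108 and 139 in WT and 10.4 and 11.7 in Gli3R, with Mix at 110.

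Erythroid-like cells showed the most changed genes of any class, 381 higher and 89 lower. The adult-type beta-globin gene Hbb-bt (chromosome 7, 103812524 to 103813996, minus strand) rose from 42.3 ± 22.8 CPM in WT to 1348 ± 423 in Gli3R (log2 5.02, SE 0.53, adjusted p = 0.0080, n = 2 each). Hbb-bs, its neighbour, stood at 1213 and 651 against 13020 and 14310. Emx2 rose from 2 UMIs over both WT libraries to 135 and 132 CPM (adjusted p = 0.0011), and Myzap from 0.625 to 47.6 (log2 6.28). The tetraspanin gene Tspan8 (4.92) and Cish, a target of STAT5 and cytokine signalling (4.37), rose as well. Dmtn, which encodes a protein of the red cell membrane skeleton, fell by 5.81 on the log2 scale (SE 0.44, adjusted p = 0.0041), and Rragd by 4.95. The other named genes lower there were Vamp8 (-4.68), the stress gene Gadd45a (-3.98) and Tmem256 (-3.39).

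The WT cells of this class lay mainly in clusters 0, 2 and 10 and the Gli3R cells in clusters 1 and 14, whose leading genes include Hbb-bt and Hbb-bs, so the comparison sets largely separate groups of erythroid-like cells side by side. The embryonic globin gene Hbb-bh1 stood at 66650 and 62160 CPM in WT and 53610 and 65660 in Gli3R, and the embryonic Hbb-y at 16880 and 8875 against 31530 and 50510 (log2 1.71, SE 0.46, adjusted p = 0.11). Both were chosen after their values were seen. No list of this class passed with an estimated correlation (smallest adjusted p 0.88). At the preset correlation FGF ligands were lower as a list (adjusted p = 0.0034, 2 of 3 members), with Fgf3 at 8.72 and 27.0 CPM against 0.351 and 0.728 (log2 -4.85, SE 0.70, adjusted p = 0.018) and Fgf15 at -5.66 (0.036). FGF/ERK response genes were higher (0.0034, 2 of 7 over all genes, 4 rising and 1 falling adjusted over the list alone), with Egr1 (3.43, SE 0.28, 0.0041) and the feedback inhibitor Spry2 (3.16, 0.042) past the threshold and Spry1 at -2.25. Dissociation and heat stress genes were higher beside them (0.0034, 4 of 15), with Atf3 (4.91), Jund (2.20), Jun (1.70) and the same Egr1. The neural and endoderm list (0.0034, Afp at 4.05) and cardiac contractile genes (0.0082, Tnni1 at 2.03) were higher too, the former beside the visceral endoderm-like share of 3.09% in Gli3R 2. The Hedgehog list did not pass (0.65).

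In all, 470 of 13502 genes passed in erythroid-like cells. Their number was 229 without WT 1 (175 higher), 578 without WT 2 (338 higher), 555 without Gli3R 1 (400 higher) and 378 without Gli3R 2 (316 higher). Of 20 called genes named here or leading a list 15 kept their call without each library. Without WT 1 the calls of Afp, Gadd45a, Jun and Spry2 ended (adjusted p 0.058 to 0.11), without WT 2 those of Afp, Fgf15 and Spry2 (0.073 to 0.085), without Gli3R 1 those of Jun and Spry2 (0.056 to 0.10) and without Gli3R 2 those of Afp and Fgf15 (0.054 to 0.064). Among the lists, FGF ligands (0.10) and neural and endoderm genes (0.073) lost their call without WT 2, FGF/ERK genes (0.12) and contractile genes (0.17) without Gli3R 1, and contractile genes (0.088) without WT 1.

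**Figure D4:**
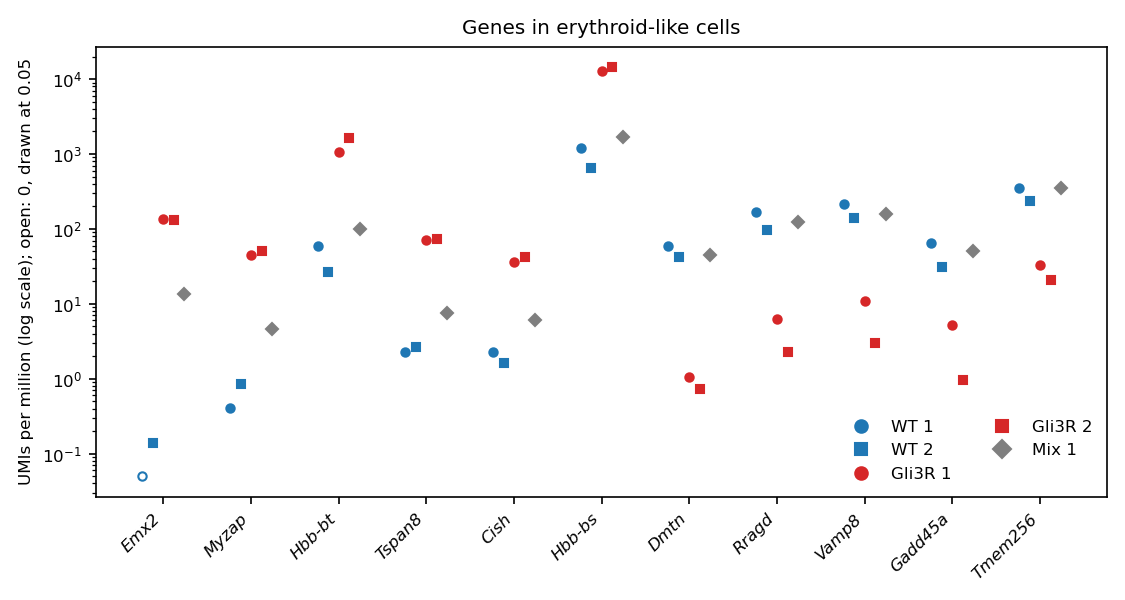
CPM on a log axis in the erythroid-like cells of each library for the genes named by rule and Hbb-bs (blue, WT; red, Gli3R; grey, Mix; open symbol, a count of 0). Hbb-bt lies at 58.5 and 26.2 in WT, 1049 and 1647 in Gli3R and 98.4 in Mix.

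In extraembryonic mesenchyme and allantois-like cells both targets of the pathway fell, Ptch1 from 123 ± 21.6 to 11.1 ± 0.865 CPM (log2 -3.46, SE 0.30, adjusted p = 0.0058, n = 2 each) and Hhip (chromosome 8, 79965851 to 80058006, minus strand) from 31.6 and 32.3 to 1.04 and 0.833 (log2 -4.97, SE 0.42, adjusted p = 0.0058). Gas1 rose (2.36, SE 0.27, adjusted p = 0.024), as did the chemokine gene Cxcl13 (3.78), Nrk (3.11), the IGF binding protein gene Igfbp5 (2.79), the protease gene Prss23 (2.58) and the caveolar gene Cavin1 (2.36). The cell cycle and WNT target gene Ccnd1 fell (-2.30, SE 0.30, adjusted p = 0.046), as did Hspa8 (-3.68). WT cells of this class lay most often in cluster 7 and Gli3R cells in cluster 3, while clusters 4 and 9 held both genotypes. Ptch1 was at -2.98 within cluster 9 (SE 0.48, adjusted p = 0.051) and at -1.73 within cluster 4 (SE 0.46, 0.75). The WT level of Hhip came mainly from cluster 7 (62.0 CPM in WT 1 and 61.8 in WT 2), where the Gli3R libraries had 42 and 31 cells with 2 and 0 UMIs of it. In clusters 4 and 9 it was at 0 to 3.11 CPM in WT, so the fall of Hhip over the class may reflect its make-up of clusters, and a change within a cluster was left open. The lists of this class may reflect that make-up too. Hoxc8 is among the leading genes of clusters 7 and 9 and Col1a2 among those of clusters 3 and 4. No list was tested within a cluster.

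No list of this class passed with an estimated correlation (smallest adjusted p 0.60, that of the Hedgehog list among others). At the preset correlation the Hedgehog list was lower (adjusted p = 0.0056, 2 of 14 members falling and 1 rising over all genes, 7 falling and 2 rising adjusted over the list alone, 0.022 with fry), with Foxf1 at -1.51, Osr1 at -2.03 and Gli1 at -2.17. FGF ligands (0.0056, Fgf3 at -3.38, Fgf15 at -3.68), WNT response (0.013, Cdx4 at -2.45, Lef1 at -1.38), posterior Hox (0.015, Hoxc8 at -2.43) and S phase genes (0.017) were lower as lists. Retinoic acid response (0.0096, Rarb at 2.33), cardiac contractile (0.0070, Actc1 at 1.67), cardiac factor (0.037, Mef2c at 1.76), extracellular matrix (0.025, Col1a2 at 1.49) and neural and endoderm genes (0.013, Ttr at 2.03) were higher, the last beside the visceral endoderm-like share of 3.09% in Gli3R 2, and FGF/ERK genes did not pass (0.29, Dusp4 at -1.72) except, as lower, without WT 1 (0.0014).

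Of 13369 genes 8 were higher and 6 lower in this class. The number called was 124 without WT 1 (84 higher), 3 without WT 2 (0 higher), 61 without Gli3R 1 (34 higher) and 50 without Gli3R 2 (35 higher). It was 89 in clusters 3 and 7 alone (63 higher), 5 in cluster 4 alone (2 higher) and 15 in cluster 9 alone (10 higher). Without WT 2, 8 of the 10 called genes followed lost their call (adjusted p 0.068 to 0.23), Hhip and Gas1 among them, while Ptch1 and Hspa8 did not, and 9 of the 10 list calls ended (0.10 to 0.49). Without Gli3R 2 Ccnd1 (0.054) and 5 list calls (0.056 to 0.18) were lost, and the cardiac factor list also without WT 1 (0.096) and Gli3R 1 (0.12).

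Endothelium-like cells had less Aplnr, the apelin receptor of angioblasts and veins (175 ± 9.77 CPM in WT, 15.2 ± 4.64 in Gli3R, log2 -3.45, SE 0.33, adjusted p = 0.012, n = 2 each). Vat1 (-2.87), the arterial connexin gene Gja4 (-2.66), the corepressor gene Cbfa2t3 (-2.54) and Hspa8 (-3.54) fell too. The interferon-induced gene Rsad2 (3.27, SE 0.41) and Igfbp5 (2.84, SE 0.34) rose. No list passed here with an estimated correlation (smallest adjusted p 0.81). At the preset correlation anterior Hox genes were higher as a list (adjusted p = 0.0059, Hoxb4 at 1.49) and posterior Hox genes lower (0.028, Hoxa7 at -1.81), with retinoic acid response genes (0.019, Cyp26b1 at 5.23, SE 0.79) and neural and endoderm genes (0.0059, Ttr at 3.25) higher and S phase genes (0.0059) lower. The visceral endoderm-like share of 3.09% in Gli3R 2 stands beside Ttr here too. The Hedgehog list had an adjusted p of 0.096 with camera and 0.024 with fry, and Foxf1 was at -2.35. FGF/ERK genes did not pass (0.74).

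In this class 4 of 10344 genes were higher and 12 lower, and each of the 7 genes followed lost its call without either Gli3R library while its fold change stayed near the reported one. Aplnr was at -3.89 without Gli3R 1 and -3.16 without Gli3R 2, and Igfbp5 at 3.04 and 2.61. Without Gli3R 1 no gene passed with edgeR (adjusted p 1.0 for the 7) and without Gli3R 2 a single one did (0.20 to 0.50), against 102 without WT 1 (50 higher) and 147 without WT 2 (60 higher), where Gja4 was at 0.051. DESeq2 called 42 genes in the 4 libraries (11 higher). Cluster 5 alone gave 23 genes, 15 higher and 8 lower, and cluster 8 alone 54, 17 higher and 37 lower, so the balance of directions differed between them. Of the lists, posterior Hox genes lost their call without WT 1 (0.33), WT 2 (0.15) or Gli3R 2 (0.33), retinoic acid genes without WT 1 (0.12) or Gli3R 1 (0.12), S phase genes without WT 2 (0.079) and neural and endoderm genes without Gli3R 2 (0.079).

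Blood progenitor and megakaryocyte-like cells had 41 and 53 cells in the WT libraries against 618 and 727 in Gli3R, and 108 of 9024 genes passed, 72 higher and 36 lower. The clusters of the class differed by genotype, with 38 and 53 WT cells in cluster 13 and 3 and 0 in cluster 16, against 428 and 462 and 190 and 265 Gli3R cells. Lmo2, an adaptor of early blood and endothelial factors, fell from 228 ± 67.8 to 15.2 ± 0.634 CPM (log2 -3.76, SE 0.33, adjusted p = 0.0030, n = 2 each), and Gnb4 (-3.82), Vangl1 (-3.74), Ggct (-3.74) and Hspa8 (-3.53) fell as well. The 5 highest genes had no UMI in WT. With a floor of 3 counts over the WT group, Apold1 and Elovl7 were at least 10.3-fold higher, Kcnk6 at least 8.72-fold, the ephrin gene Efna5 at least 6.62-fold and the retinoic acid receptor gene Rarg at least 5.80-fold. Lists had a smallest adjusted p of 0.71 with an estimated correlation. At the preset correlation haemoglobin genes were higher as a list (adjusted p = 0.045, Hba-a2 at 4.55, Hbb-y at 2.66), as were endothelium genes (0.045, Esam at 3.09, Erg at 3.31) and mitochondrially encoded genes (0.045), while S phase genes were lower (0.0067) and FGF/ERK genes did not pass (0.12, Spry2 at 3.19).

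The number of genes called there was 62 without WT 1 (43 higher), 104 without Gli3R 1 (74 higher) and 98 without Gli3R 2 (77 higher). Without WT 2 it was 19, and the balance turned to 5 higher and 14 lower. Of the 16 called genes followed, 13 lost their call without WT 2 (adjusted p 0.072 to 0.28), 6 without WT 1 (0.053 to 0.12), 5 without Gli3R 1 (0.079 to 0.67) and 4 of the 15 measured without Gli3R 2 (0.11 to 0.73). Lmo2, Hspa8 and Hbb-y kept theirs without each library. The haemoglobin list was lost without WT 2 (0.16) and the endothelium (0.33) and mitochondrial lists (0.57) without WT 1.

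Posterior heart field and lateral plate-like cells had more pleiotrophin (Ptn, 91.5 ± 52.0 CPM in WT, 554 ± 90.0 in Gli3R, log2 2.86, SE 0.39, adjusted p = 0.022, n = 2 each), more Igfbp5 (2.61), more of the mesothelial gene Upk3b (2.63, SE 0.39, adjusted p = 0.029) and more Flrt2 (2.17). The make-up of the class differed by genotype, as cluster 19, of which Igfbp5 is a leading gene, held 8 and 36 of the 71 and 383 WT cells and 177 and 110 of the 574 and 383 Gli3R cells. Hbb-bs was higher too (2.84, SE 0.39), at 49.3 and 18.3 against 176 and 175 CPM. Over all cells outside the erythroid-like and blood progenitor classes it stood at 91.0, 13.9, 207 and 177 CPM in WT 1, WT 2, Gli3R 1 and Gli3R 2, and free RNA, doublets and split barcodes were not told apart as its source. Hspa8 (-3.70) and Spin2c (-1.72) fell. With an estimated correlation the smallest adjusted p of a list was 0.57. At the preset correlation retinoic acid response (adjusted p = 0.016, Crabp2 at 2.65), cardiac contractile (0.016), pharyngeal (0.017, Alx1 at 1.63), mitochondrially encoded (0.016) and EMT genes (0.040) were higher as lists, and WNT response (0.016, Ccnd1 at -1.28), haemoglobin (0.022, Hbb-bh1 at -1.60) and S phase genes (0.0077) lower. The Hedgehog list (0.23, Foxf1 at -1.89, Gas1 at 1.63) and the FGF/ERK list (0.28, Dusp6 at 1.26) did not pass.

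Here 14 of 9528 genes were higher and 4 lower, 53 passed without WT 1 (37 higher), 12 without Gli3R 1 (7 higher) and 1 without Gli3R 2 (0 higher). Without WT 2 it was 14, and the balance turned to 5 higher and 9 lower. Without Gli3R 2 each of the 7 genes followed lost its call (adjusted p 0.11 to 1.0), with 5 lost without WT 2 (0.066 to 0.21) and 3 without Gli3R 1 (0.10 to 0.23). Of the 8 list calls, 6 ended without WT 1 (0.071 to 0.68), where the haemoglobin list turned its direction, 3 without WT 2 (0.057 to 0.063), 2 without Gli3R 2 (0.13 to 0.36) and 1 without Gli3R 1 (0.17).

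In anterior cardiopharyngeal-like cells, the class with second heart field and pharyngeal genes, the Hedgehog list was lower at the preset correlation (adjusted p = 0.0046) but not with an estimated correlation (adjusted p = 0.37, as for each list called here), and passed with fry (0.019). Of 10 members 0 passed over all genes, and 4 fell and 1 rose adjusted over the list alone. Ptch1 stood at 52.0 and 58.5 CPM in WT and 7.04 and 7.30 in Gli3R (log2 -2.89, SE 0.43, adjusted p = 0.088), Osr1 at -2.20, Foxf1 at -4.66, Gas1 at 1.35 and the heart gene Nkx2-5 at -1.17. FGF/ERK (0.030, Egr1 at 1.43), BMP response (0.0046, Id3 at 0.77), EMT (0.016, Twist1 at 1.46), glycolysis (0.0046) and dissociation stress genes (0.0040, Junb at 1.71 and Fos at 1.03) were higher and S phase genes lower (0.016). Egr1 belongs to both the FGF/ERK and the stress list. Among single genes 0 of 8128 were higher and 3 lower with edgeR (442 with an unadjusted p under 0.05), and 5 higher and 10 lower with DESeq2. Hspa8 (-3.31, SE 0.35, adjusted p = 0.013) and the pseudogenes Rps13-ps1 and Rps15a-ps8 passed. The predicted gene Gm14513, higher in Gli3R (3.02, 0.057), and then Podxl (-2.09, 0.076) followed by p without passing.

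With DESeq2 size factors 25% of the calls of that class were higher in place of 0%. The number called was 46 without WT 1 (26 higher), 44 without WT 2 (18 higher), 15 without Gli3R 1 (7 higher) and 22 without Gli3R 2 (9 higher). Of the 7 list calls, 6 ended without WT 2 (0.078 to 0.32; Hedgehog 0.29) and without Gli3R 1 (0.057 to 0.19; Hedgehog 0.057), and the EMT list without WT 1 (0.15) or Gli3R 2 (0.075).

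Somite-like cells had higher FGF/ERK response genes as a list (adjusted p = 6.9e-06, 5 of 11 rising adjusted over the list alone, 0 over all genes), but not with an estimated correlation (adjusted p = 0.64, as for the other lists called here) or with fry (0.21). Spry2 was at 1.32, Egr1 and Dusp6 both at 0.97, Ier3 at 2.56 and Spry1 at 1.48, and the list held without each library. Aldh1a2, the enzyme that makes retinoic acid in somites, fell from 216 ± 50.1 to 19.7 ± 13.4 CPM (log2 -3.20, SE 0.43, adjusted p = 0.017, n = 2 each), and Hspa8 fell (-3.59). Ptch1 was at -2.93 (adjusted p = 0.071), Gas1 at 1.19, Foxc2 at -1.06, and the Hedgehog list did not pass (0.33). Glycolysis (0.0012, Hk2 at 1.03), BMP response (0.019, Id3 at 0.92) and EMT genes (0.019, Snai2 at 1.56) were higher and S phase genes lower (0.029). Of 7454 genes 0 were higher and 3 lower with edgeR, where 369 had an unadjusted p under 0.05, and DESeq2 called 3 higher and 6 lower. The counts were 37 without WT 1 (21 higher), 20 without WT 2 (5 higher), 13 without Gli3R 1 (4 higher) and 13 without Gli3R 2 (7 higher). Of the 5 list calls 4 ended without Gli3R 1 (0.070 to 0.41). BMP and glycolysis genes were lost without WT 2 (0.16 to 0.32) and EMT and S phase genes without WT 1 (0.060 to 0.066).

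In caudal mesoderm-like cells, of which the Gli3R libraries held 65 and 21, posterior Hox genes were higher as a list (adjusted p = 1.1e-15, 9 of 9 adjusted over the list alone, 0 over all genes). The list had an adjusted p of 0.47 with an estimated correlation and 0.33 with fry, and passed without each library at the preset one. Hoxc8 was at 56.4 and 36.5 CPM in WT and 247 and 148 in Gli3R (log2 2.24, SE 0.46, adjusted p = 0.31), Hoxc9 at 2.89, Hoxa9 at 2.44 and Hoxb7 at 2.35. BMP response genes were also higher (0.015, Msx2 at 1.57, adjusted p = 0.85 with an estimated correlation), a call lost without WT 1 (0.073) or Gli3R 1 (0.83). Hedgehog (0.24), FGF ligand (0.31) and FGF/ERK genes (0.78) did not pass, with Fgf17 at 2.12, Fgf8 at 0.95 and T at -0.28. With a minimum of 2000 UMIs or with the replicate number as a block, 0 genes were called in this class. In the main fit, of 4918 genes 0 were higher and 3 lower with edgeR (118 with an unadjusted p under 0.05) and likewise with DESeq2. Hspa8 (-3.35, SE 0.46) and both pseudogenes passed, and without Gli3R 1 Hspa8 (0.21) and Rps15a-ps8 (0.44) lost their call. Leaving out a library gave 30 without WT 1 (19 higher), 59 without WT 2 (20 higher), 3 without Gli3R 1 (1 higher) and 12 without Gli3R 2 (5 higher).

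Cardiomyocyte-like cells, with 41 to 128 cells per library, had less Igfbpl1 (160 ± 31.6 CPM in WT, 6.55 ± 0.739 in Gli3R, log2 -4.47, SE 0.55, adjusted p = 7.7e-04, n = 2 each), Ifitm1 (-3.12, SE 0.48, adjusted p = 0.0096), Hapln3 (-4.04, SE 0.74, 0.047) and Hspa8 (-3.75). Left-right genes (adjusted p = 0.0084, Tdgf1 at -0.89, Lefty2 at -1.15) and S phase genes (0.025) were lower as lists and glycolysis genes higher (0.018), and FGF/ERK genes did not pass (0.59). Each of these 3 calls had an adjusted p of 0.61 with an estimated correlation. Of 5241 genes 1 was higher and 5 lower, and with DESeq2 size factors 0% of the calls were higher in place of 16.7%. Counts were 33 without WT 1 (15 higher), 109 without WT 2 (56 higher), 7 without Gli3R 1 (0 higher) and 10 without Gli3R 2 (3 higher), and Hapln3 lost its call without Gli3R 1 (0.61). Each list call ended without WT 2 (0.051 to 0.24) and without Gli3R 2 (0.089 to 0.25), the S phase call also without WT 1 (0.21) and the glycolysis call without Gli3R 1 (0.056).

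In unnamed cluster 20, an epithelial group with Epcam and Otx2, Hspa8 (-3.50, SE 0.49, adjusted p = 0.0021) and Rps13-ps1 fell, and no gene of 3955 was higher with edgeR or DESeq2 (105 with an unadjusted p under 0.05 in edgeR). With DESeq2 size factors in edgeR 6 were called, 50.0% of them higher. Dqx1 had no UMI in Gli3R, at least 14.8-fold below WT against a floor of 3 counts over the group (adjusted p = 0.063). Hbb-bs (2.79, 0.063) and Acta2 (2.90, 0.088) did not pass either, the former beside its level outside the blood classes given above. Mitochondrially encoded (0.0096) and matrix genes (0.030, Hapln1 at 1.46) were higher as lists, but not with an estimated correlation (adjusted p = 0.77). FGF/ERK genes did not pass (0.66). In that cluster 15 passed without WT 1 (10 higher), 52 without WT 2 (37 higher), 2 without Gli3R 1 (0 higher) and 14 without Gli3R 2 (11 higher). Both list calls ended without WT 1 (0.45) and Gli3R 1 (0.24), and the mitochondrial one without Gli3R 2 (0.12).

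Over the 10 classes, 51 of 201 pairs of list and class passed with camera at the preset correlation, 34 higher and 17 lower, 0 with an estimated correlation and 4 with fry, which were the Hedgehog list in extraembryonic, endothelium-like and anterior cardiopharyngeal-like cells and S phase genes in endothelium-like cells (0.024).

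A few genes differed in nearly every class. These were chosen after their values were seen. Of 550 genes called in at least 1 class, 67 were called in 2 or more and 6 in 3 or more. Hspa8 and Rps13-ps1 were called in 10 of 10 classes, Rps15a-ps8 in 7, Gm28438 and Igfbp5 in 4 and Hbb-bs in 3. Rps13-ps1 (chromosome 8, 87047689 to 87048226, plus strand) and Rps15a-ps8 (chromosome 4, 53791070 to 53791456, minus strand) are annotated as processed pseudogenes of ribosomal protein genes, so their reads may be shared with the parent genes. Over whole libraries Rps13-ps1 stood at 360 and 398 CPM in WT and 0.778 and 1.27 in Gli3R (log2 -8.72, SE 0.44, adjusted p = 0.0014). In somite-like cells it had no UMI in Gli3R, at least 132-fold below WT against a floor of 3 counts over the group.

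**Figure D5:**
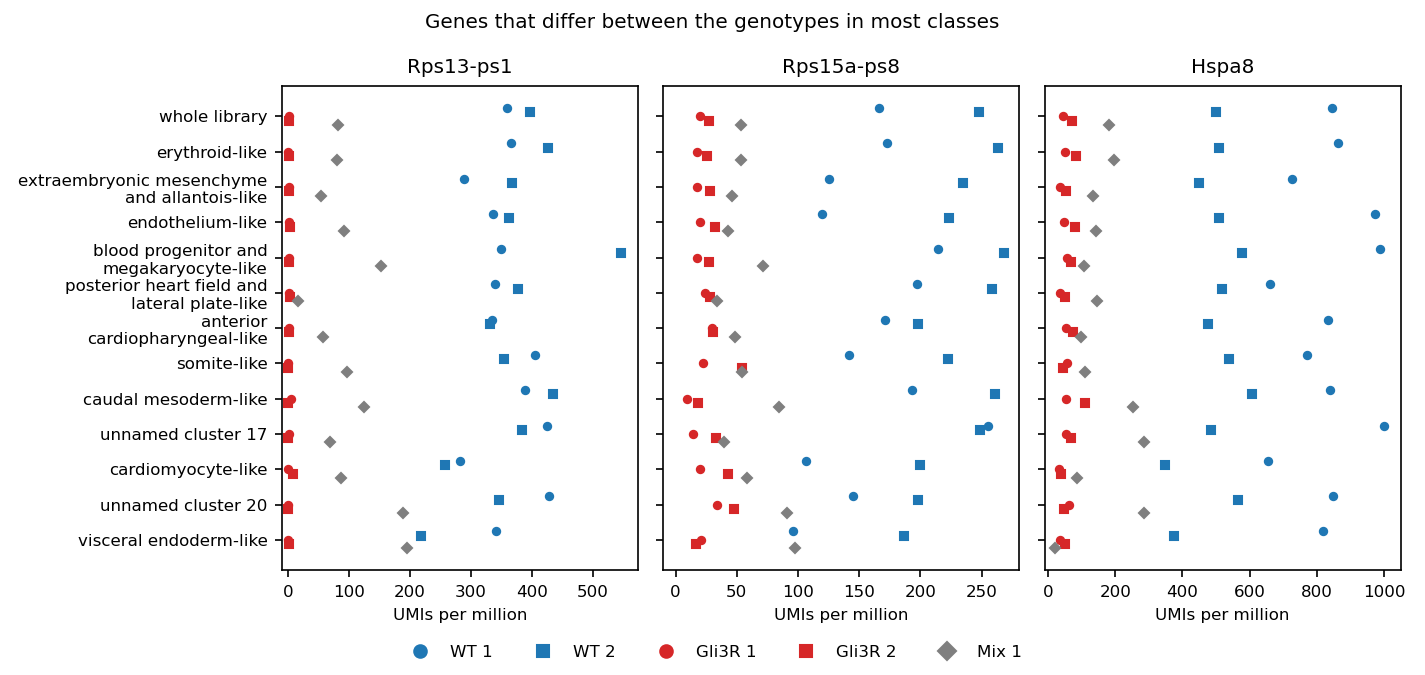
CPM of Rps13-ps1, Rps15a-ps8 and Hspa8 per library, over whole libraries and in each class (blue, WT; red, Gli3R; grey, Mix). Over whole libraries Rps13-ps1 lies at 360 and 398 in WT, 0.778 and 1.27 in Gli3R and 81.2 in Mix, and Hspa8 at 846 and 500, 45.8 and 70.8, and 182.

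The Mix library, prepared from both genotypes, had 67.1% erythroid-like cells (95% interval 65.8% to 68.3%, counting error only), 4.66% endothelium-like, 2.72% blood progenitor and 1.59% caudal cells. Gene levels were placed on the way from the WT mean (0%) to the Gli3R mean (100%), and the median over the called genes taken. It was 15.5% for whole libraries, 10.6% for erythroid-like, 14% for lateral plate-like, 30.6% for extraembryonic and 34.0% for endothelium-like cells. It was 67.0% for blood progenitor, 69.2% for cardiomyocyte-like, 70.3% for caudal, 74.5% for somite-like and 88.1% for anterior cardiopharyngeal-like cells. The last 3 medians rest on 3 genes each, most of them Hspa8, Rps13-ps1 and Rps15a-ps8, which lay near Gli3R in erythroid-like cells as well (79.1%, 80.0% and 83.7%). Ptch1 lay at 23% in anterior cardiopharyngeal-like, 24.6% in somite-like and -13.9% in caudal cells, so these medians depend on the genes called and do not compare the classes. Ptch1 stood at 25.8 CPM over the whole Mix library and at 110 in its extraembryonic cells. These are values of 1 library and carry no test.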

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

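The share of Mix 1 cells in some classes and clusters lay above the 95% counting intervals of both WT libraries, and Mix 1 entered no comparison. These were the blood progenitor and megakaryocyte-like class, at 2.72% of cells, and its clusters 13 (2.24%) and 16 (0.479%), the erythroid-like clusters 0 (30.8%), 1 (6.07%) and 10 (12.9%), and the extraembryonic clusters 3 (1.74%) and 4 (5.31%).

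Of the 9 tests below, the one of the beta-globin locus was written before its result was seen and the other 8 after the pattern and its neighbouring values were seen. Values within Mix 1 carry counting error only.

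Ptch1 was lower in the extraembryonic mesenchyme and allantois-like cells of the Gli3R libraries. A different make-up of the class would leave no difference within a cluster that both genotypes share, and within cluster 9 the log2 fold change was -2.98 (SE 0.48, adjusted p = 0.051), which argues against make-up alone, though it was -1.73 in cluster 4. Embryo age as labelled would remove the difference among WT 1, WT 2 and Gli3R 1, which share an age label. There it was -3.48 (SE 0.60), with Gli3R 1 alone for its genotype, so the SE holds no spread between Gli3R libraries. Mix 1, labelled younger, had the WT level of 110 CPM. It pools both genotypes, and the protocol gives it the age of the other libraries, so this level cannot test age. Within Mix 1 the Ptch1 level of cells near cluster 3 was 0.133 (0.0601 to 0.257) times that of cells near cluster 7, on 9 and 234 UMIs, against 0.495 (0.282 to 0.809) within WT. That leaves open whether the fall is a response to Gli3R or to the actual stage of the embryos, which could differ from the label.

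The erythroid-like cells of the Gli3R libraries had more adult-type globin and a set of 470 changed genes. The test for a sequence variant at the beta-globin locus asked whether the changed genes gather on chromosome 7. That chromosome held 8.94% of them and 7.36% of the tested genes. A variant of that locus could hardly gather 470 genes there, so this result could not decide. Whether such a variant raised Hbb-bt and Hbb-bs was not tested. Embryo age as labelled would remove the difference in WT 1, WT 2 and Gli3R 1 alone, where Hbb-bt stood at 4.66 (SE 0.55). With a single Gli3R library there, the SE holds no spread between Gli3R libraries. In Mix 1, 9.34% (8.40 to 10.4) of erythroid-like cells lay in clusters 1 and 14, which held 0.921% and 1.55% of those of WT and 94.1% and 97.3% of those of Gli3R. This leaves open whether Gli3R acts within the cells whatever the stage of the embryo, since the number of Gli3R erythroid cells in Mix 1 is not known. In clusters 0, 2 and 10 of Mix 1 the genes went both ways. Emx2 was low there (2.47 CPM), as in WT, while Rps13-ps1 (67.8 CPM) lay below the 337 to 450 CPM of these clusters in WT. Gm28438 stood at 16.5 CPM there and had no UMI in the WT cells of these clusters.

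Rps13-ps1 and Rps15a-ps8 were lower in nearly every class of the Gli3R libraries. A difference between whole libraries in mapping or counting would spread the UMIs of Rps13-ps1 evenly over the cells of Mix 1, but the number of its erythroid-like cells with a UMI was 0.281 times the Poisson number, against 0.809 and 0.838 in WT and a median of 0.942 over genes of like level. In Mix 1 this ratio was 0.733 for Rps15a-ps8 (like genes 0.949) but 0.968 for Gm28438 (like genes 0.955). Gm28438 was thus spread like other genes of its level, and a difference between libraries was left open for it. The pseudogenes lie on different chromosomes, so a single sequence variant would not lower both. Variants carried together by some of the pooled embryos would lower both in the same cells. Rps15a-ps8 was 10.7 times higher in Mix 1 cells with an Rps13-ps1 UMI than in cells with none, against 3.53 and 3.20 in WT. Variants carried together could give this, and whether other causes would give it too was not tested. Hspa8 was also uneven between cells (0.438 in Mix 1, 0.730 and 0.852 in WT) but ran the other way, at 0.580 times the level in Mix 1 cells with an Rps13-ps1 UMI (0.788 and 0.891 in WT), and no explanation was tested for it. A response to Gli3R would lower Rps13-ps1 in clusters 1 and 14 of Mix 1, where it was 2.80 times the level of clusters 0, 2 and 10, but as the genotype of single Mix 1 cells is not known this leaves a response open.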

How the results depend on the processing

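Of 188 values of class shares under an alternative, 169 kept their direction and side of the threshold, 10 lost the threshold, 7 gained it and 2 turned. Of 139 counts of changed genes 60 stayed within 1.5 times the reported count and 79 did not, and of 14 counts of lists 10 did. Values of single named genes held in 4951 of 5639 cases, with 460 passing the threshold anew, 144 no longer passing and 84 turning in sign. Values of single lists held in 313 of 543 cases, with 216 no longer passing, 6 passing anew and 8 turning. The other clusterings kept 92.1% to 96.3% of the cells in their class, and resolution 0.5 gave no value for anterior cardiopharyngeal-like cells and cluster 20. Depth limits the small classes, where 3955 genes could be tested in cluster 20 against 18047 over whole libraries. Merged barcodes, the crossed block and the tests of single clusters were chosen after seeing the data. For each change below the cause was not tested.

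Among the shares, TMM factors over classes gave visceral endoderm-like 1.75 (log2 ratio, no longer past the threshold). With the blood classes left out of the total the log2 ratio of the extraembryonic class was -0.017 and that of the cardiomyocyte-like class -0.038, both turned and neither past the threshold before, and that of the visceral endoderm-like class was 1.64. The replicate number gives no known pairing of libraries. Over genes, libraries of the same number deviated together (correlation 0.194), and over class shares in opposite directions (-0.667). With that number as a block blood progenitor 3.55, caudal -2.71 and visceral endoderm-like 2.16 no longer passed. A crossed block, of WT 1 with Gli3R 2 and WT 2 with Gli3R 1, brought 7 more classes past the threshold (erythroid-like -1.09, endothelium-like 1.63, lateral plate-like 1.18, cardiopharyngeal-like 1.07, somite-like -0.95, cluster 17 1.44 and cluster 20 -1.24).

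DESeq2 called 702 in whole libraries, 780 in erythroid-like cells, 95 in extraembryonic cells, 42 in endothelium-like cells, 15 in cardiopharyngeal-like cells and 9 in somite-like cells. No filter on low counts gave 1134 in whole libraries, 1308 in erythroid-like cells, 232 in extraembryonic cells, 145 in endothelium-like cells, 492 in blood progenitor cells, 71 in lateral plate-like cells, 51 in cardiopharyngeal-like cells, 33 in somite-like cells, 10 in caudal cells, 25 in cardiomyocyte-like cells and 15 in cluster 20. The replicate block gave 1262 in whole libraries, 2153 in erythroid-like cells, 121 in extraembryonic cells, 292 in endothelium-like cells, 630 in blood progenitor cells, 196 in lateral plate-like cells, 168 in cardiopharyngeal-like cells, 113 in somite-like cells, 0 in caudal cells and 16 in cardiomyocyte-like cells. Size factors of DESeq2 in edgeR gave 6 in cluster 20. A minimum of 2000 UMIs gave 10 in endothelium-like cells, 9 in lateral plate-like cells, 17 in cardiopharyngeal-like cells and 0 in caudal cells, and one of 500 UMIs 8 in cardiopharyngeal-like cells and 3 in cardiomyocyte-like cells. Merging barcodes gave 9 in lateral plate-like cells, 15 in cardiopharyngeal-like cells and 8 in somite-like cells, and keeping doublets 5 in cardiopharyngeal-like cells, 6 in caudal cells and 5 in cluster 20. Over whole libraries the count was 29 with each class set to its mean share and 2 without the blood classes. Within the extraembryonic class it was 89 in clusters 3 and 7 and 5 in cluster 4, and within the endothelium-like class 54 in cluster 8. Camera with an estimated correlation passed 0 lists over whole libraries and 0 pairs of list and class, and fry passed 0 and 4.

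Some single genes turned in sign, none of them past the threshold as reported. These were Smo -0.0065 and Boc -0.010 in whole libraries with DESeq2, Smo -0.0065 and Boc -0.0081 in whole libraries with its size factors, Smo -0.028 and Fgf18 0.020 in whole libraries and Fgf3 0.11 in caudal cells with the block, and Fgfr1 0.23 in cluster 20 with doublets kept. A minimum of 2000 UMIs turned Smo -0.039 in whole libraries, Msx2 -0.42 in cardiopharyngeal-like cells, Id3 -0.57 in caudal cells and mt-Nd4 -0.20 and Fn1 -0.20 in cluster 20, one of 500 UMIs Msx1 -0.11 in somite-like cells, and merged barcodes Msx2 -0.30 in cardiopharyngeal-like cells. With each class set to its mean share the values were Smo -0.29, Boc -0.26, Fgf17 1.10, Fgf18 0.79, Etv5 -0.00090, Fgfr1 -0.023, Fgfr2 -0.13, Spred2 -0.016, Hes7 0.30, Notch1 -0.070, Gata4 -0.026 and Hoxa11 -0.18 in whole libraries. Without the blood classes they were Gli2 -0.056, Smo -0.18, Boc -0.41, Fgfr1 -0.083, Fgfr2 -0.099, Spred1 -0.20, Spred2 -0.19, Etv4 -0.43 and Pdk1 0.32 in whole libraries.

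Leaving out 1 library at a time leaves 1 library in a group, which is then assumed to vary like the other group. The log2 ratio of shares ranged from 3.31 to 3.81 for the blood progenitor class, from -3.66 to -1.74 for the caudal class and from 1.04 to 3.22 for the visceral endoderm-like class. These calls ended without WT 2 for the blood progenitor (adjusted p = 0.063), caudal (0.12) and visceral endoderm-like class (0.16), and without Gli3R 2 for the caudal (0.23) and visceral endoderm-like class (0.43). The number of changed genes ranged from 98 to 1476 in whole libraries, 229 to 578 in erythroid-like cells, 3 to 124 in extraembryonic cells, 0 to 147 in endothelium-like cells, 19 to 104 in blood progenitor cells and 1 to 53 in lateral plate-like cells. It ranged from 15 to 46 in cardiopharyngeal-like cells, 13 to 37 in somite-like cells, 3 to 59 in caudal cells, 7 to 109 in cardiomyocyte-like cells and 2 to 52 in cluster 20. The highest count came without WT 2 in whole libraries, in erythroid-like, endothelium-like, caudal and cardiomyocyte-like cells and in cluster 20, and without WT 1 in extraembryonic, lateral plate-like, cardiopharyngeal-like and somite-like cells.

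Over whole libraries the log2 fold changes that turned when 1 library was left out ranged as follows for Smo (-0.45 to 0.37), Boc (-0.32 to 0.43), Fgf10 (-0.67 to 0.44), Fgf18 (-1.13 to 2.32), Fgfr1 (-0.059 to 0.87), Fgfr2 (-0.025 to 0.61) and Etv1 (-0.30 to 0.97). The same range is given for Spred1 (-0.23 to 1.24), Spred2 (-0.20 to 0.97), Spry4 (-0.72 to 0.40), Il17rd (-0.77 to 0.71), Dusp4 (-0.66 to 0.62), Etv4 (-0.61 to 0.65) and Notch1 (-0.027 to 1.74). It is also given for Hoxb1 (-0.054 to 1.36), Hoxa11 (-0.55 to 1.31), Pdk1 (-1.25 to 0.0083), Pfkl (-1.64 to 0.11), mt-Co1 (-0.50 to 1.28) and Cfc1 (-1.93 to 0.011). In extraembryonic cells they ranged for Fgf10 (-0.95 to 0.43) and Epcam (-1.69 to 0.67). In lateral plate-like cells they ranged for Cdx4 (-2.24 to 0.57), mt-Co1 (-0.24 to 1.27), Snai1 (-0.012 to 0.85) and Vim (-0.087 to 1.60). In cardiopharyngeal-like cells they ranged for Spry2 (-0.00032 to 1.72). In somite-like cells they ranged for Msx1 (-0.24 to 0.27) and Cdh2 (-0.034 to 1.68). In caudal cells they ranged for Gli3 (-0.11 to 0.51), Fgf8 (-0.15 to 1.27), Fgf3 (-7.66 to 0.15) and Fgfr1 (-2.28 to 0.36). In cluster 20 they ranged for Egr1 (-0.19 to 0.93), Fgfr1 (-1.93 to 0.14), mt-Nd6 (-0.057 to 0.88) and Lamb1 (-0.33 to 1.64). The direction of the FGF/ERK list turned in some of these settings, with an adjusted p of 0.0196 to 0.551 over whole libraries, 0.00135 to 0.914 in extraembryonic cells, 0.117 to 0.982 in endothelium-like cells, 0.342 to 0.781 in caudal cells and 0.670 to 0.935 in cluster 20. So did that of the haemoglobin list in lateral plate-like cells (1.0e-04 to 0.679) and the Hedgehog list in caudal cells (0.483 to 0.865).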

Other observations

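Within Mix 1, the erythroid-like cells of clusters 1 and 14, the clusters that held most Gli3R erythroid-like cells, differed from those of clusters 0, 2 and 10 in some of the genes that differed between the genotypes. Emx2 stood at 114 CPM (95% interval 100 to 130, counting error only) against 2.47 (1.83 to 3.26), Hbb-bt at 582 (550 to 616) against 46.5 (43.5 to 49.6) and Hbb-bs at 7728 against 1046. Ptch1 stood at 5.63 (2.91 to 9.83) against 13.6 (12.1 to 15.4), and Hspa8 at 136 (121 to 153) against 202 (196 to 208). Other genes did not follow the difference between genotypes. Rps13-ps1 (190 against 67.8) and Rps15a-ps8 (90.5 against 49.6) were higher in clusters 1 and 14 though lower in Gli3R, and the predicted gene Gm28438, with no UMI in WT erythroid-like cells, stood at 17.8 (12.6 to 24.5) against 16.5 (14.7 to 18.4). These genes were chosen after their values were seen, and clusters were formed on gene levels that include some of them.

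Haemoglobin RNA was present outside the blood classes in every library. Hbb-bh1 stood there at 4980 CPM in WT 1, 1458 in WT 2, 981 in Gli3R 1, 1080 in Gli3R 2 and 4356 in Mix 1, against 66650, 62160, 53610, 65660 and 65550 in erythroid-like cells. For Hbb-bh1, Hba-x and Hbb-y the highest values outside blood were in WT 1 and Mix 1, the libraries with the largest share of erythroid-like cells. For Hbb-bs (207 and 177 CPM) and Hbb-bt (13.3 and 17.9 CPM) they were in Gli3R 1 and Gli3R 2, whose erythroid-like cells had the most of both.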
